A study of Mus musculus with 8 samples.

How the data were processed

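RNA from the ascending aorta of 8 mice was measured on Illumina expression arrays, 1 array per mouse. Mucopolysaccharidosis VII (MPS VII) is a lysosomal storage disease caused by loss of beta-glucuronidase, the enzyme encoded by Gusb, and its mouse model develops a widened ascending aorta. The labels put 3 mice in the normal group, 3 in the group of MPS VII mice with a dilated aorta and 2 in the group of MPS VII mice whose aorta was not dilated. Each title names a separate animal, so the replicates are mice. The labels give ages of 5.8, 6.4 and 7 months for the normal mice, 7.8, 9.1 and 6 months for the mice with dilatation and 5.8 and 6.7 months for those without, and every group holds females and males.

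The values analysed are the deposited intensities of 25697 probes on a linear scale, which the authors had already processed. GenomeStudio and Partek are named, with no role, in the submitters' processing notes, and the steps between scanner and table are not given in the sources used here. The values themselves show that a background had been subtracted, since about 28% of them lie below 0 on every array, and that the arrays had been brought to a common distribution, since the sorted values of the 8 arrays differ by at most 0.94 intensity units. The array medians lie between 17.75 and 17.99, the highest value is 64846.4 on every array, and the scale is not centred. Because all arrays share 1 distribution, a change in the total amount of RNA cannot be seen in these values. A second deposited table of signals before normalization was not used here: 16 of its columns have names that match no single sample.

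Before the data were examined, the groups, the tests, the gene lists, the rule for naming genes and the alternatives were fixed. The planned start from unnormalized signals with neqc and a filter on detection p-values needed the second table. In its place, log2 of the deposited intensity plus an offset of 50 was used, which keeps values below 0 and understates the change of dim genes. The noise was taken from the values below 0 (SD 11), and a probe counted as above background on an array when its intensity passed 25.6, the one-sided 0.01 bound of that noise. Probes above background on at least 2 of the 8 arrays were kept (12913 probes). Between 45% and 45.2% of the probes were above background on each array.

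The platform annotation gives 1 gene symbol for 23141 probes, several for 0 and none for 2556. All 23141 matched the gene table of assembly GRCm38.p6 through their Entrez identifier, and 0 symbols had to be updated. No genome build is named in the sources used here, so no coordinates are given and the gene table was used only for names and for which genes lie next to each other. Each gene was represented by its probe with the highest mean over the 8 arrays, and unnamed probes were kept as they were, which left 10040 genes for testing, of which 8955 are named and 1085 are unnamed probes. Among the further probes of genes past the threshold in dilated minus normal, 91.6% had the same sign as the probe used.

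A linear model with a mean per group was fitted to all 8 arrays in limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 5 residual and 4.05 prior degrees of freedom. The 4 contrasts were taken from it, namely dilated minus normal, not dilated minus normal, dilated minus not dilated, and the mean of both MPS VII groups minus normal. A gene was called changed at a two-sided Benjamini-Hochberg adjusted p under 0.05. With 3 arrays against 3, an exact permutation test of a single gene could not go below p = 0.1, so the p-values rest on limma's model. Standard errors (SE) of log2 differences are those of limma, and intensities are given as mean ± SD over the mice of a group. A group in which no array lay above background has only an upper bound. For such genes the ratio is given as at least N-fold, the mean log2 value of the brighter group against the mean over the dim group's arrays of the higher of the background bound and the measured value. The number of arrays limits the precision.

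Gene lists were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 30 lists with at least 5 measured members. Of 33 fixed lists, the sex chromosome list served only to check labels, and the B and plasma cell list and the erythroid list each had 4 measured members. Each list was also tested with a correlation estimated from the data and with fry, a rotation test of whether the genes of a list move, on balance, in 1 direction. With the estimated correlation, 0 lists passed the threshold in each of the 4 contrasts, and that adjusted p is given beside most lists that passed with the preset correlation. The cathepsin and the immediate early and heat shock lists had estimated correlations of -0.015 and -0.00519, below the preset value. In dilated minus normal their camera p still went from 6.17e-07 to 0.00325 and from 8.51e-06 to 0.00472. A higher correlation therefore does not account for the loss of these 2 calls. The number of members that changed is given over all genes tested and, where stated, adjusted over the list alone. The named genes are those set by the fixed rule. For dilated minus normal the rule took the 12 largest rises and 12 largest falls among named genes past the threshold whose groups did not overlap, and 6 and 6 for the other contrasts. Where no gene passed, it took the 5 with the smallest p. To these it added Gusb, up to 4 members of each list with the smallest p in dilated minus normal, and Ctss, Ctsk, Ctsd, Mmp12, Eln and Acta2. C3, also fixed by name, is not analysed here. Where a gene outside this rule is named, the text says so.

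The fit was tested on simulated data with the noise of these arrays, in 10 runs over 10040 genes with 200 changed genes each. For dilated minus normal it recovered 75.4% of genes changed by 1 on the log2 scale and 99.2% of those changed by 2, and 7.8% of those changed by 0.5, with 5.12% of the calls false. For dilated minus not dilated the recovery was 5.2% at 0.5, 64.8% at 1 and 97.4% at 2, with 4.03% false. The p cutoff of the adjustment depends on how many genes change, and the real data gave 2031 and 0 calls in these 2 contrasts. The recovery rates therefore do not carry over to the real data. A list shifted by 0.5 in dilated minus normal was called in 10 of 10 runs, with 0 other lists called. The simulated genes varied independently, while the genes of some real lists vary together. The correlations estimated from the data went from -0.0619 (chondrocyte and osteogenic) to 0.776 (MHC class II). The runs therefore cannot show whether list calls with the preset correlation hold in the real data. The sex given in the labels matched the array's sex-linked genes in 8 of 8 mice.

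Alternatives were another background step, an intensity floor with no offset, cyclic loess on top of the deposited normalization, other filters on dim probes, every probe as its own unit, an intensity trend, array weights, sex or age as a covariate, only the arrays compared, the sample number as a block, a fold limit of 1.5, other list tests and leaving out each array in turn. An offset of 100 and the mean of the adipocyte list as a covariate were added after seeing the data. The deposited processed values, planned as an alternative, are the ones analysed throughout. A block for the slide was not run because no slide is named in the sources used here.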

Results

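The ascending aortas of 8 mice were profiled: 3 came from normal animals, 3 from animals with MPS VII whose aorta had widened, and 2 from animals with MPS VII whose aorta had not. The 8 arrays had medians of 17.75 to 17.99 intensity units, and 45% to 45.2% of the probes on each lay above background. Across genes, the correlation of 2 arrays of 1 group was 0.972 to 0.989 over 7 pairs, and that of 2 arrays of different groups 0.926 to 0.985 over 21 pairs. Not dilated replicate 2 correlated more closely with dilated replicates 1 and 2 (0.983 and 0.985) than with not dilated replicate 1 (0.979). The first principal component held 55.2% of the variance, with the 3 normal arrays at 28.5 to 33.0 and the 5 MPS VII arrays at -36.6 to -9.53. The 2 MPS VII groups overlapped on it, with dilated arrays at -36.6 to -12.8 and the others at -15.8 and -9.53.

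Gusb, the gene that is defective in MPS VII, was lower in both MPS VII groups. Its intensity was 1086 ± 90.2 (SD, n = 3) in normal aorta, 197 ± 17.7 (n = 3) in dilated aorta and 118 ± 9.64 (n = 2) in MPS VII aorta without dilatation (probe 6180678). It fell by 2.20 on the log2 scale in dilated aorta (SE 0.12, limma adjusted p = 0.000114) and by 2.75 without dilatation (SE 0.13, limma adjusted p = 6.56e-05), and each of the 5 MPS VII arrays lay below each of the 3 normal arrays. The 2 further probes of Gusb lay close to background. The level without dilatation was lower than with dilatation in these 5 mice, a log2 difference of 0.55 that did not pass the test (SE 0.13, limma adjusted p = 0.301).

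**Figure D1:**
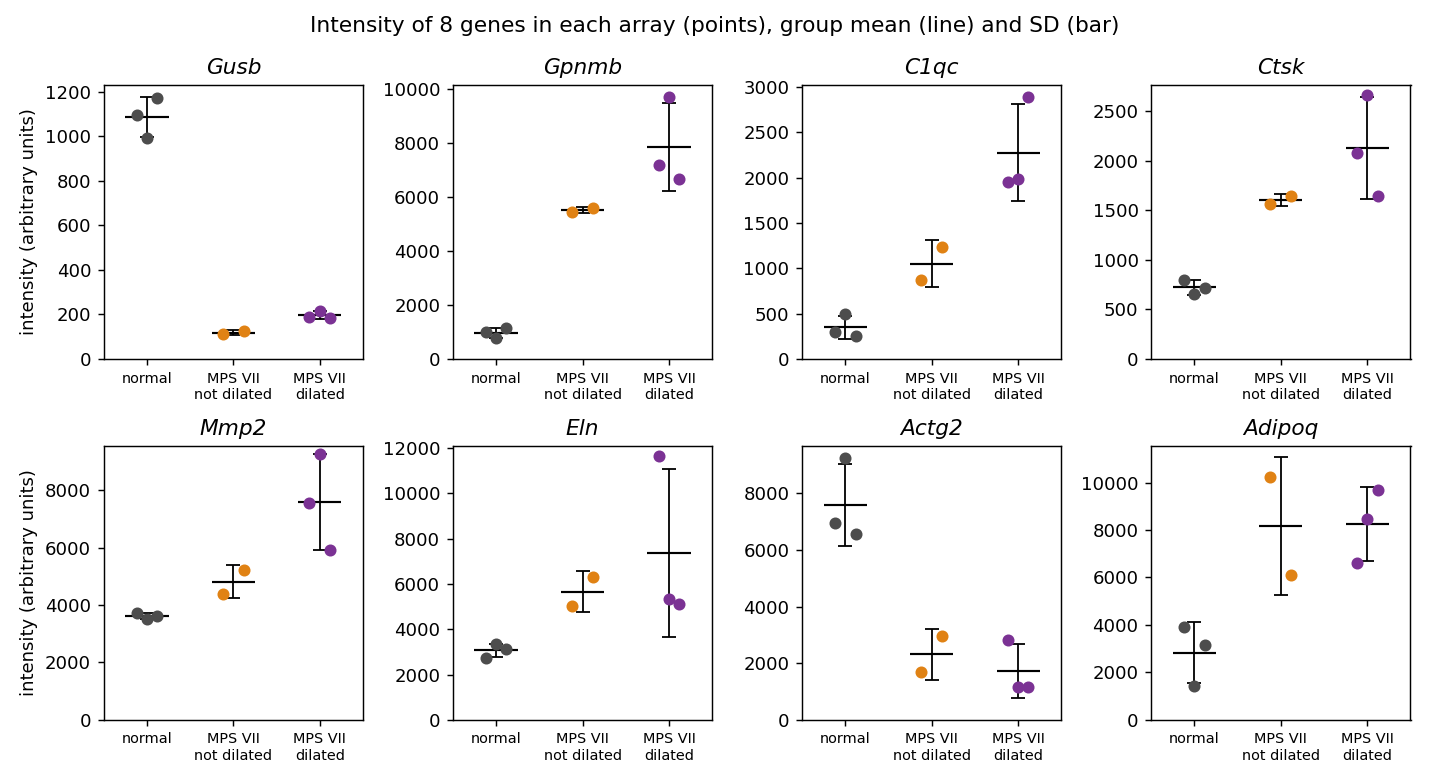
Intensity (arbitrary units, linear axis from 0) of 8 genes in each of the 8 arrays, with points for mice, a line for the group mean and a bar for the SD. Gusb lies at 1086 on average in normal aorta against 197 and 118 in the MPS VII groups, while Gpnmb lies at 977 against 7844 and 5514.

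The comparison of dilated MPS VII aorta with normal aorta asks what differs in the diseased vessel wall. By camera's test with the preset correlation, the lists of macrophage, complement, chemokine, lysosomal and antigen presentation genes lay higher in the dilated aorta, and those of contractile smooth muscle, adventitial fibroblast and immediate early and heat shock genes lay lower. With an estimated correlation 0 lists passed (smallest adjusted p = 0.0709). Fry called 12 lists, among them macrophage, complement, lysosomal and MHC class II (fry adjusted p = 0.00478, 0.011, 0.00137 and 0.0176). Contractile smooth muscle, adventitial fibroblast and immediate early and heat shock also passed by fry (0.0203, 0.00478 and 8e-05). The cytokine and chemokine list did not (fry adjusted p = 0.0832), nor did the endothelial, adipocyte, interferon, neutrophil, proliferation and oxidative phosphorylation lists. Of 10040 genes, 2031 changed (limma adjusted p under 0.05), 985 of them higher and 1046 lower (1118 and 846 with cyclic loess on top of the deposited normalization), with 406 rises and 206 falls of at least 2-fold. The groups did not overlap for 42.5% of the genes, where chance gives 10%.

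The macrophage list had the smallest camera p of the 30 lists, with 15 of 21 measured members higher and 0 lower (18 higher and 1 lower when adjusted over the list alone) and a median log2 difference of 1.86. The camera adjusted p was 1.55e-12 with the preset correlation, and the adjusted p = 0.282 with an estimated correlation. Ms4a7, a membrane protein of macrophages, went from 18.4 ± 25.9 to 985 ± 289 (limma adjusted p = 0.000294), and since 2 of the 3 normal arrays lay below background, the size of its log2 difference depends on the offset and is not given. Trem2, a lipid-sensing receptor of macrophages, went from 48.6 ± 20.3 to 877 ± 125 (log2 difference 3.24, SE 0.23, limma adjusted p = 0.000203). Fcer1g, the signalling chain shared by Fc receptors, rose by 2.61 (SE 0.21, limma adjusted p = 0.000255) and Fcgr4, an IgG receptor, by 3.23 (SE 0.29, limma adjusted p = 0.000484). The lectin gene Clec4d lay below background in all 3 normal aortas and at 437 ± 243 in the dilated ones, at least 5.96-fold higher (limma adjusted p = 0.000571).

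In the complement list, 6 of 14 measured members rose and 0 fell (camera adjusted p = 7.57e-06, and adjusted p = 0.282 with an estimated correlation). The study's own publication singled out complement in these aortas, so this list is not independent evidence of its direction. All 3 chains of C1q, which starts the classical pathway, were higher: C1qa went from 171 to 862, C1qb from 700 to 3962 and C1qc from 349 to 2276, rises of 2.02, 2.42 and 2.56 on the log2 scale (limma adjusted p at most 0.00116). C2, a protease of the same pathway, rose by 1.32 (limma adjusted p = 0.00752).

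Of 23 measured cytokine and chemokine genes, 10 rose and 1 fell (camera adjusted p = 7.57e-06, and adjusted p = 0.38 with an estimated correlation). The list mean lay 2.485 above normal in dilated replicate 3, against 0.732 and 1.014 in the other dilated aortas. Ccl21a, which guides lymphocytes and dendritic cells, had the largest rise by the rule for named genes, from 57.9 ± 67.1 to 2422 ± 805 (log2 difference 4.66, SE 0.54, limma adjusted p = 0.00104). Its SD in normal aorta exceeds its mean there, so the size and rank of this rise depend on the offset. Ccl21b rose by 4.41 and Ccl21c, below background in normal aorta, was at least 14.2-fold higher, but these genes are near-identical copies, so which of the 3 was measured is uncertain. Ccl8 rose by 3.82 (SE 0.52, limma adjusted p = 0.002), with a wide spread among dilated aortas (2197 ± 2061). Cxcl16 rose by 1.43 (limma adjusted p = 0.00187). All 7 measured MHC class II genes rose (camera adjusted p = 2.19e-05, and adjusted p = 0.322 with an estimated correlation), among them H2-Ab1 by 1.48 and Cd74, the invariant chain, by 1.39. In the toll-like receptor and NF-kappa-B list 6 of 22 rose and 3 fell (camera adjusted p = 0.00522, and adjusted p = 0.288 with an estimated correlation). The adhesion molecules Icam1 and Vcam1 in that list rose by 1.80 and 1.86, Cd14 by 1.93 and Tlr7 by 1.21. In the interferon response list 5 of 22 rose and 1 fell (camera adjusted p = 0.00058, and adjusted p = 0.393 with an estimated correlation), with Ifit3 going from 594 to 1466.

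Among lysosomal enzymes and membrane proteins, 18 of 36 rose and 1 fell (camera adjusted p = 1.65e-07, and adjusted p = 0.134 with an estimated correlation). Gpnmb, a glycoprotein of lysosomes and phagocytes, rose by 2.94 (SE 0.18, limma adjusted p = 0.000168). Hexa, a subunit of beta-hexosaminidase, rose by 1.06 and Man2b1, lysosomal alpha-mannosidase, by 0.99. Hyal1, a lysosomal hyaluronidase, was the member that fell, by 1.83 (SE 0.20, limma adjusted p = 0.000834). Of 13 cathepsins and relatives 7 rose and 0 fell (camera adjusted p = 6.17e-06, and adjusted p = 0.0709 with an estimated correlation). Ctsk, a collagen- and elastin-degrading protease, went from 722 ± 73.6 to 2126 ± 512 (log2 difference 1.47, SE 0.17, limma adjusted p = 0.0011), and Lgmn went from 720 to 2150 and Ctsz from 469 to 893. Ctsl lay below background in normal aorta and was at least 2.00-fold higher in dilated aorta (limma adjusted p = 0.000511). Ctss and Ctsd did not pass the test, with log2 differences of 0.28 (limma adjusted p = 0.383) and 0.42 (limma adjusted p = 0.142), on probes at 41.6 and 59.5 in normal aorta, close to background. In the cholesterol and lipid handling list 5 of 13 rose and 0 fell (camera adjusted p = 9.42e-05, and adjusted p = 0.217 with an estimated correlation), led by Apoe, from 811 ± 158 to 4757 ± 799.

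Matrix proteases and elastic fibre genes moved in both directions. In the list of matrix metalloproteinases and relatives 7 of 20 rose and 2 fell, and the list did not pass (camera adjusted p = 0.0726). Mmp3, or stromelysin, rose by 1.96 (SE 0.29, limma adjusted p = 0.00323) and the gelatinase Mmp2 by 1.04 (SE 0.17, limma adjusted p = 0.00448). Mmp12, macrophage elastase, lay below background in normal aorta and at 106 ± 96.3 in dilated aorta, at least 1.84-fold higher (limma adjusted p = 0.0135). Of 11 protease inhibitors 3 rose and 1 fell (camera adjusted p = 0.0331, and adjusted p = 0.282 with an estimated correlation), among them Timp4 by 1.38 and Timp1 by 2.24, or by 1.41 without dilated replicate 3. Of 15 elastic fibre genes 5 rose and 2 fell (camera adjusted p = 0.31). Eln, which encodes elastin, went from 3066 ± 298 to 7373 ± 3719 (log2 difference 1.15, SE 0.29, limma adjusted p = 0.0235), and Lox and Fbln2 rose by 1.24 and 1.62. Ltbp4, a latent TGF-beta binding protein, fell by 1.46 (SE 0.12, limma adjusted p = 0.000296).

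The contractile smooth muscle list was lower, with 12 of 18 members down and 1 up (15 and 1 when adjusted over the list alone), a median log2 difference of -1.05 and a camera adjusted p = 7.57e-06 (adjusted p = 0.38 with an estimated correlation). Actg2, smooth muscle gamma-actin, went from 7588 ± 1463 to 1713 ± 960 (log2 difference -2.23, SE 0.35, limma adjusted p = 0.00391). Myocd, a coactivator of smooth muscle genes, fell by 1.74, Cnn1, or calponin, by 1.17 and Cald1, or caldesmon, by 0.96. Acta2, smooth muscle alpha-actin, did not pass, at 50835 ± 5424 against 40909 ± 10195 near the top of the intensity scale (log2 difference -0.34, limma adjusted p = 0.246). The 2 further Acta2 probes, with means of 7907 and 5023, had log2 differences of the other sign, 0.46 and 0.50. In the adventitial fibroblast list 6 of 14 fell and 0 rose (camera adjusted p = 0.0173, and adjusted p = 0.322 with an estimated correlation), among them Pi16 by 1.48, Clec3b by 1.37 and Tnxb by 1.37. Of 19 immediate early and heat shock genes 9 fell and 0 rose (camera adjusted p = 3.01e-05, and adjusted p = 0.0709 with an estimated correlation). Fos fell by 2.66 (SE 0.30, limma adjusted p = 0.000968), and the log2 differences of Hspa1a, Dusp1, Atf3 and Jun were -2.53, -2.08, -1.71 and -1.07.

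Other large falls were those of Wif1, a secreted Wnt inhibitor, from 715 ± 187 to 52.4 ± 15.2 (log2 difference -2.88, SE 0.19, limma adjusted p = 0.000168), Tcap by 2.80, Optc, an extracellular leucine-rich proteoglycan, by 2.67, Ppp1r1b by 2.65, Hspb7 by 2.39 and the potassium channel subunit Kcnab1 by 2.26. Npy1r, a neuropeptide Y receptor, fell by 2.16 and Fbxl22 by 2.13. Further large rises were those of Gpr176, from a mean of 16.7, below the background bound, to 823, Cyp2e1 by 3.63, AA467197 by 3.37 and Wfdc17 by 3.18. In the proteoglycan list 4 of 30 rose and 7 fell (camera adjusted p = 0.875), where the median log2 difference was above 0 (0.00502) and the mean and the test's direction below it (-0.0189), with Sdc3 up by 2.09 and Gpc6 down to 132 ± 9.26 from 628 ± 13.3. In the collagen list 1 of 13 rose and 1 fell (camera adjusted p = 0.31), Col1a1 by 1.24 and Col4a5 by -1.04. In the chondrocyte and osteogenic list 1 of 9 rose, Comp by 1.59, and 2 fell, among them Acan by 1.22 (camera adjusted p = 0.579).

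Markers of other cell types also moved with the group. In the adipocyte list 7 of 17 rose and 0 fell (camera adjusted p = 3.01e-05, and adjusted p = 0.393 with an estimated correlation), with Adipoq, or adiponectin, going from 2817 ± 1284 to 8255 ± 1544 and Car3, a carbonic anhydrase abundant in fat, from 349 ± 166 to 4314 ± 1688. The mean log2 intensity of that list was 9.93 ± 0.454 in normal aorta, 10.92 ± 0.304 in dilated aorta and 11.12 ± 0.505 without dilatation. In the endothelial list 8 of 19 rose and 0 fell (camera adjusted p = 0.000142, and adjusted p = 0.38 with an estimated correlation), among them Emcn by 1.84 and Egfl7 by 1.24. Smaller list shifts that passed were those of the neutrophil list, 1 of 9 up (camera adjusted p = 0.0451, and adjusted p = 0.52 with an estimated correlation), the proliferation list, 2 of 13 up and 1 down (camera adjusted p = 0.0138, and adjusted p = 0.52 with an estimated correlation), and the oxidative phosphorylation list, 1 of 25 up (camera adjusted p = 0.0406, and adjusted p = 0.717 with an estimated correlation). The neutrophil call ended under 17 of 24 alternatives, among them the left-out dilated replicate 3, whose list mean lay 2.08 above normal against 0.391 and 0.517 in the other dilated aortas, and the oxidative phosphorylation call ended or turned direction under 8 of 24. The proliferation and protease inhibitor calls ended with age as a covariate. The T and NK cell, autophagy, TGF-beta, unfolded protein response, cardiomyocyte, skeletal muscle and Schwann cell lists did not pass, with camera adjusted p of 0.0759, 0.81, 0.875, 0.576, 0.875, 0.576 and 0.493.

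The count of 2031 changed genes was 1086 without normal replicate 1, 1165 without normal replicate 3 and 1342 without dilated replicate 2. The calls of Eln, Timp1, Hspb7 and Col4a5 ended without any 1 of the 3 normal replicates, that of Eln also with age as a covariate (limma adjusted p = 0.0621), those of Hspb7 and Col4a5 also without dilated replicate 3 and with values floored at 16, that of Hspb7 with array quality weights, and those of Col4a5 and Pi16 without dilated replicate 2. The calls of Pi16 and Mmp12 ended without normal replicate 1, and those of Pi16 and Comp without normal replicate 3. Without dilated replicate 1 the log2 differences of Eln and Hspb7 were 0.76 and -1.55. The count was 3320 with array quality weights and 238 with the mean of the adipocyte list as a covariate, an alternative added after seeing the data, under which 99.6% of the 2031 genes had the same sign, their median absolute log2 difference went from 0.757 to 0.635 and their median SE from 0.161 to 0.246, and the endothelial, fibroblast, adipocyte, interferon and toll-like receptor lists no longer passed (camera adjusted p = 0.135, 0.139, 0.817, 0.135 and 0.0558).

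**Figure D2:**
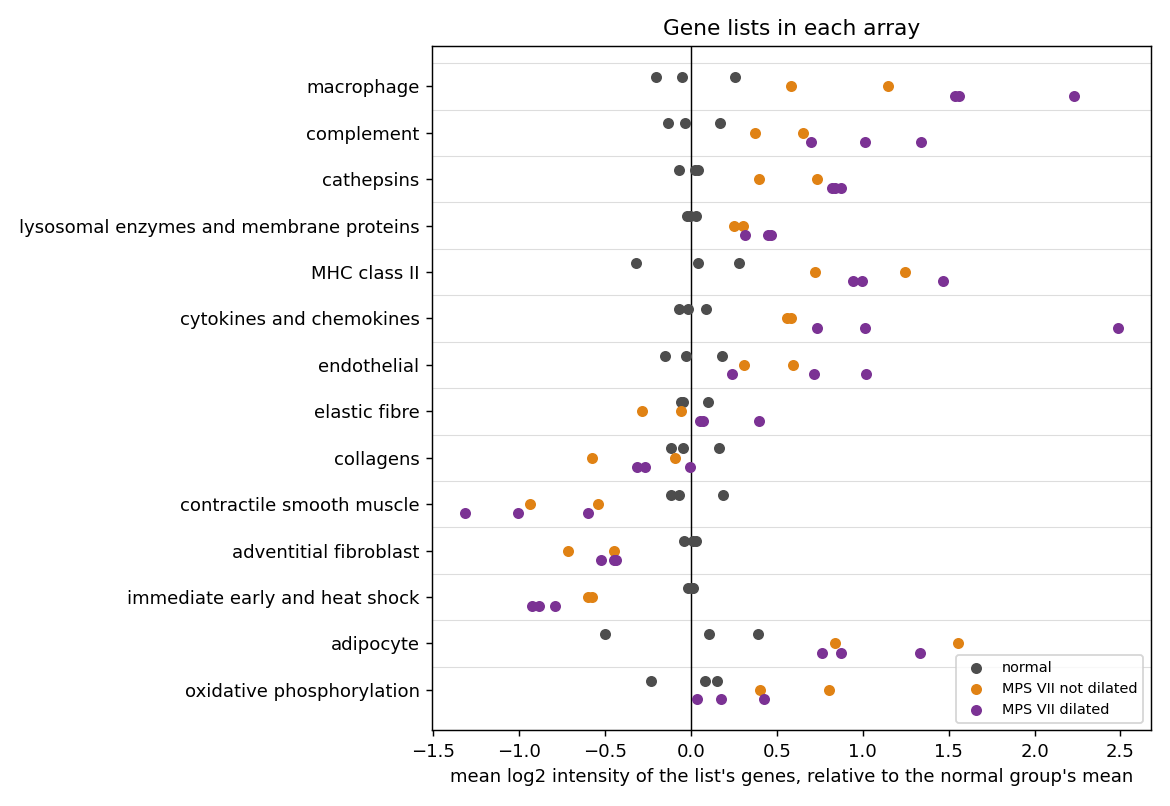
Mean log2 intensity of the measured genes of 14 lists in each array, relative to the mean of the normal group (horizontal axis, log2 units), with 1 point per mouse coloured by group. The macrophage points of the 3 dilated aortas lie above those of the other 5, and the contractile smooth muscle points of all 5 MPS VII aortas lie below those of the 3 normal aortas.

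MPS VII aorta without dilatation was compared with normal aorta to show what differs in the diseased vessel when it is not widened. Fewer genes passed here, with 2 arrays against 3. By camera's test with the preset correlation, the macrophage, lysosomal, antigen presentation, adipocyte and oxidative phosphorylation lists lay higher and the contractile smooth muscle, fibroblast and immediate early lists lower, though most members of each did not pass singly, apart from 4 of 7 in antigen presentation. With an estimated correlation 0 lists passed (smallest adjusted p = 0.137). Of 10040 genes 1006 changed (limma adjusted p under 0.05), 486 higher and 520 lower, with 244 rises and 123 falls of at least 2-fold. With cyclic loess on top of the deposited normalization the split was 531 higher and 378 lower. The groups did not overlap for 50.7% of genes, where chance gives 20%.

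In the macrophage list 8 of 21 rose and 0 fell (camera adjusted p = 8.53e-06, and adjusted p = 0.461 with an estimated correlation). Ms4a7 reached 448 ± 200 (limma adjusted p = 0.00634) and Trem2 250 ± 122 (log2 difference 1.57, SE 0.26, limma adjusted p = 0.0135), while Fcer1g did not pass (log2 difference 0.69, limma adjusted p = 0.0868). Of 14 complement genes 4 rose (camera adjusted p = 0.00157, and adjusted p = 0.461 with an estimated correlation), among them C1qa by 0.88, C1qb by 1.32 and C1qc by 1.49, and again this list is not independent evidence. Of 7 MHC class II genes 4 rose (camera adjusted p = 6.52e-05, and adjusted p = 0.461 with an estimated correlation), Cd74 by 1.28 and H2-Ab1 by 1.19 among them. Of 23 cytokine and chemokine genes 3 rose and 1 fell (camera adjusted p = 0.0236, and adjusted p = 0.58 with an estimated correlation). Ccl8 rose by 2.80 and Cxcl14 lay below background in normal aorta and was at least 3.95-fold higher (limma adjusted p = 0.0162).

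Of 36 lysosomal genes 5 rose and 1 fell (camera adjusted p = 5.54e-05, and adjusted p = 0.237 with an estimated correlation). Gpnmb rose by 2.45 (SE 0.20, limma adjusted p = 0.00139) and Man2b1 by 0.78, Hyal1 fell by 1.37, and Hexa had a log2 difference of 0.56 that just missed the threshold (limma adjusted p = 0.0509). Of 13 cathepsins and relatives 4 rose (camera adjusted p = 0.000988, and adjusted p = 0.137 with an estimated correlation), with Ctsk up by 1.10, Ctsz by 0.54 and Ctsl at least 1.58-fold higher. In the list of matrix metalloproteinases and relatives 0 of 20 changed (camera adjusted p = 0.694), and the log2 differences of Eln, Lox and Fbln2 were 0.87, 0.22 and 0.25 (limma adjusted p = 0.108, 0.586 and 0.492). Mmp12, at 33.6 ± 3.1, did not pass (limma adjusted p = 0.167), nor did Ctss, Ctsd and Acta2 (limma adjusted p = 0.983, 0.85 and 0.734). The further Acta2 probes had log2 differences of 1.04 and 1.21 here, against -0.12 for the probe used.

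The oxidative phosphorylation list had 7 of 25 members up and 0 down (camera adjusted p = 2.49e-07, and adjusted p = 0.461 with an estimated correlation). Sdhb, a subunit of succinate dehydrogenase, rose by 1.46, Cyc1 by 1.26 and Cox5a by 1.10. In the adipocyte list, which moved with it, 7 of 17 rose (camera adjusted p = 1.64e-06, and adjusted p = 0.461 with an estimated correlation), Car3 by 3.65, Cidec by 1.83, Dgat2 by 1.75 and Adipoq by 1.59. In the cardiomyocyte list 3 of 10 rose (camera adjusted p = 0.00105, and adjusted p = 0.137 with an estimated correlation). These were Fabp3, a fatty acid binding protein also made in brown fat, by 1.83, Cox6a2, a cytochrome oxidase subunit, at least 1.29-fold, and Myl3, a myosin light chain at 72.8 against 21.8 and named here after its values were seen. The protease inhibitor, autophagy, elastic fibre, collagen, proteoglycan, toll-like receptor and TGF-beta lists did not pass (camera adjusted p = 0.294, 0.943, 0.51, 0.0685, 0.0683, 0.134 and 0.51), and in the autophagy list the median log2 difference was -0.13 while the mean was 0.03. Cyp2e1 rose by 2.97, and Hbb-b2, a beta-globin gene, lay below background in all 3 normal arrays and was at least 5.46-fold higher (limma adjusted p = 0.00372).

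Of 18 contractile smooth muscle genes 3 fell (11 when adjusted over the list alone; camera adjusted p = 0.000133, and adjusted p = 0.461 with an estimated correlation), Cnn1 by 1.24 and Cald1 by 1.16 among them. Of 14 fibroblast genes 6 fell (camera adjusted p = 0.00105, and adjusted p = 0.237 with an estimated correlation), Pi16 by 1.70 and Mfap5 by 1.49 among them. Of 19 immediate early and heat shock genes 5 fell (camera adjusted p = 0.000563, and adjusted p = 0.137 with an estimated correlation), among them Atf3 by 1.40 and Jun by 1.04. The largest falls were those of Wif1 by 3.01, Gusb by 2.75, Kcnab1 by 2.24, Optc by 2.19, Itih4 by 2.15 and the potassium channel Kcnk1 by 2.07. The endothelial, cholesterol and lipid, interferon response, neutrophil and T and NK cell lists also passed upwards, with camera adjusted p of 0.00509, 0.00105, 0.00636, 0.00837 and 0.0432 and, with an estimated correlation, adjusted p of 0.461, 0.237, 0.47, 0.461 and 0.58.

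The 1006 genes were 81 without not dilated replicate 1, 195, 300 and 551 without normal replicates 3, 1 and 2, 574 without not dilated replicate 2, and 659 and 1551 without dilated replicates 2 and 3, which enter this comparison only through the spread. Without each array in turn, Gusb, Wif1, Car3, Ms4a7, Gpnmb, Ctsl, Kcnab1, Kcnk1, Atf3, Cald1 and Hbb-b2 passed every time, and every other gene named here as changed failed to pass without at least 1 array, apart from Myl3, for which no alternative was run. The T and NK cell call ended or turned direction under 10 of 24 alternatives, the cytokine call ended with cyclic loess and without not dilated replicate 2, the interferon call without that array, and the neutrophil call with a filter of 4 arrays above background, and fry called 8 lists where camera called 17. With the adipocyte mean as a covariate, added after seeing the data, 2 genes and 10 lists passed, the oxidative phosphorylation, contractile smooth muscle and cytokine lists turned direction (camera adjusted p = 0.903 each), and 99.6% of the 1006 genes had the same sign, with a median absolute log2 difference of 0.653 against 0.873 and a median SE of 0.278 against 0.18.

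Dilated and not dilated MPS VII aortas were compared to find what goes with the widening itself. No single gene passed the threshold, while by camera's test with the preset correlation the lists of macrophage, complement, chemokine and matrix protease genes lay higher in dilated aorta and those of oxidative phosphorylation and cardiomyocyte genes lower. With an estimated correlation 0 lists passed (smallest adjusted p = 0.0901). With limma, 0 of 10040 genes changed (smallest adjusted p = 0.0507), and 909 genes had an unadjusted p under 0.05. The groups did not overlap for 25% of genes, where chance gives 20%.

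The 5 genes with the smallest p were all higher in the 3 dilated aortas than in both others. Sfrp1, a secreted Wnt regulator, lay at 1915 ± 382 against 579 ± 131 (log2 difference 1.64, SE 0.19, limma adjusted p = 0.0507) and Ccn4, a matricellular protein of the Wnt pathway, at 783 ± 70.0 against 228 ± 52.4 (log2 difference 1.59, SE 0.19, limma adjusted p = 0.0507). Fcer1g lay at 3095 ± 296 against 807 ± 305 (log2 difference 1.92, SE 0.23, limma adjusted p = 0.0507). Ddah1 and Aldh3b1 had log2 differences of 1.77 and 1.21 (limma adjusted p = 0.0932 and 0.119). The differences of Ctsk, Mmp12, Eln and Acta2 were 0.37, 0.73, 0.28 and -0.21 (limma adjusted p = 0.635, 0.62, 0.867 and 0.855).

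The macrophage list had a median log2 difference of 0.92 (camera adjusted p = 3.99e-14, and adjusted p = 0.253 with an estimated correlation), with 12 of 21 members higher when adjusted over the list alone. The medians of the cytokine and chemokine, complement, cathepsin, and matrix metalloproteinase lists were 1.00, 0.51, 0.34 and 0.31 (camera adjusted p = 2.71e-06, 0.00154, 0.00306 and 0.00489), with adjusted p of 0.35, 0.339, 0.241 and 0.253 with an estimated correlation. The elastic fibre list had a median of 0.29 (camera adjusted p = 0.00326, and adjusted p = 0.331 with an estimated correlation). The oxidative phosphorylation list had a median of -0.44 (camera adjusted p = 2.14e-09, and adjusted p = 0.339 with an estimated correlation) and the cardiomyocyte list one of -0.73 (camera adjusted p = 2.68e-06, and adjusted p = 0.0901 with an estimated correlation). Relative to normal, the oxidative phosphorylation means of the arrays overlapped, at 0.0351 to 0.425 with and 0.403 to 0.801 without dilatation. Both group means of that list lay above normal (0.212 and 0.602). The adipocyte list, with a median of -0.20, did not pass (camera adjusted p = 0.117).

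With sex as a covariate 19 genes passed, 18 higher and 1 lower, among them Trem2 at 1.76, C1qa at 1.22 and Dusp1 at -1.46 (limma adjusted p = 0.0201, 0.027 and 0.0201). Counts of 1 to 4 came with array quality weights (3), normexp (3), an offset of 100 (3), no filter on dim probes (4) and the adipocyte mean as a covariate (1), always with Fcer1g among them, and without dilated replicate 1, not dilated replicate 2 or dilated replicate 3 there were 3, 2 and 1. The cathepsin and elastic fibre calls ended without not dilated replicate 1 and the cytokine call without dilated replicate 3. With age as a covariate the lysosomal, proteoglycan and protease inhibitor calls ended, and fry called 1 list, cardiomyocyte (adjusted p = 0.0345), where camera called 13.

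The mean of both MPS VII groups was compared with normal aorta for what the disease shows with or without dilatation. Car3, Ccl8 and Cyp2e1 had the largest rises besides Ms4a7 and the Ccl21 copies, by 3.55, 3.31 and 3.30 (limma adjusted p at most 0.00273). Wif1, Gusb, Optc, Tcap, Kcnab1 and Hspa1a had the largest falls, with log2 differences of -2.95, -2.48, -2.43, -2.36, -2.25 and -2.23 (limma adjusted p at most 0.0088). Of 10040 genes 2444 changed (limma adjusted p under 0.05), 1113 higher and 1331 lower, and 32.1% of genes had groups that did not overlap, where chance gives 3.57%. With cyclic loess the split was 1255 higher and 998 lower. The macrophage list had 13 of 21 members up and 1 down (camera adjusted p = 2.38e-09, and adjusted p = 0.32 with an estimated correlation), the lysosomal list 16 of 36 up and 1 down (camera adjusted p = 1.83e-06, and adjusted p = 0.179 with an estimated correlation), the adipocyte list 11 of 17 up (camera adjusted p = 7.41e-06, and adjusted p = 0.401 with an estimated correlation) and the contractile smooth muscle list 12 of 18 down (camera adjusted p = 3.15e-05, and adjusted p = 0.427 with an estimated correlation). The 2444 genes were 1176 without normal replicate 3, 1317 without normal replicate 1 and 1552 without not dilated replicate 1, and 1437 of them had a fold of at least 1.5. With the adipocyte mean as a covariate 67 passed, while 96.6% of the 2444 genes had the same sign, with a median absolute log2 difference of 0.504 against 0.647 and a median SE of 0.247 against 0.143. That covariate left 8 lists of 18, without the adipocyte, contractile smooth muscle and oxidative phosphorylation lists among others (camera adjusted p = 0.828, 0.348 and 0.115).

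**Figure D3:**
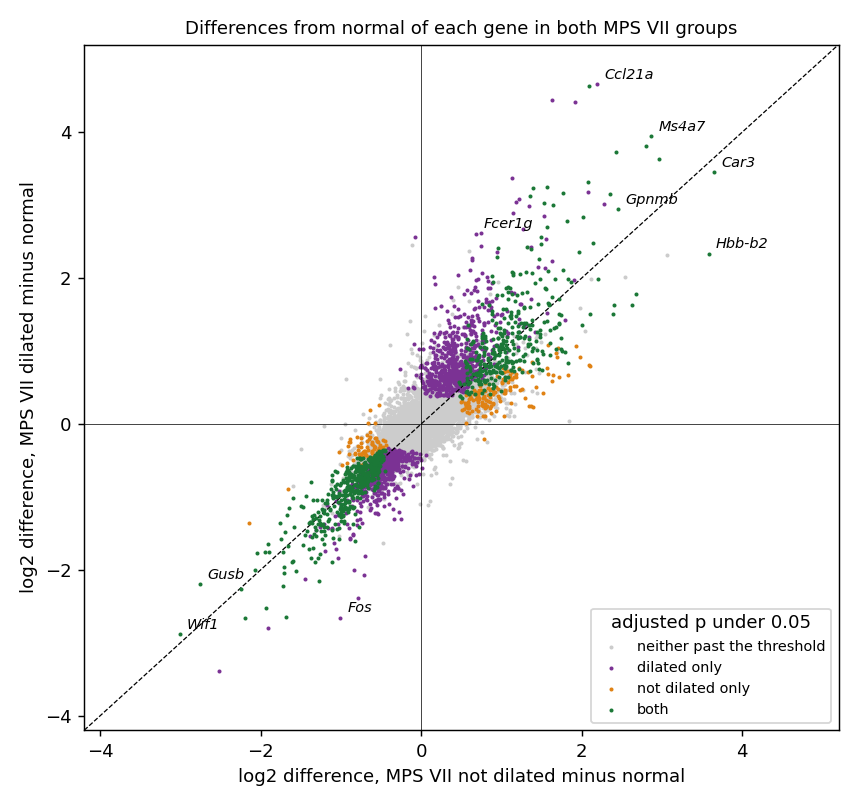
Log2 difference from normal of each gene without dilatation (horizontal axis) and with dilatation (vertical axis), coloured by which comparison had a limma adjusted p under 0.05, with the line of equal differences dashed. Both axes share the 3 normal arrays, and the correlation across genes is 0.839.

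Both MPS VII groups differed from normal aorta in similar directions. Across the 10040 genes, which are not independent replicates, the log2 differences of the 2 comparisons correlated at 0.839, where unchanged groups set against the same 3 normal arrays gave 0.445 on average and at most 0.478 over 100 simulations. The covariance was 0.224 against a simulated 0.0178 (at most 0.0199), and the difference of 0.206 leaves out what the shared normal arrays add. The sign was the same for 83.7% of genes, against 64.7% in the simulations. The simulated genes varied independently, while real genes vary together. The highest simulated values are therefore not a bound on what unchanged groups could give. Of the changed genes, 341 were higher in both comparisons (47.7 for independent lists), 445 were lower in both (54.2) and 0 changed in opposite directions. Part of the excess of this overlap over independent lists may come from the shared normal arrays, which were too few to be divided. Without not dilated replicate 2 the correlation was 0.744.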

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

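Of the tests in this part, those on the share of smooth muscle cells, on the amount of fat in each sample and on heart muscle were chosen only after the result was seen. The fit with the adipocyte mean as a covariate was also added after seeing the data. Between dilated and not dilated MPS VII aortas, 13 gene lists differed by camera's test with the preset correlation, and 0 did with an estimated correlation (smallest adjusted p = 0.0901). The macrophage list lay higher in dilated aorta (camera adjusted p = 3.99e-14), as did the cytokine and chemokine list (2.71e-06), the complement list (0.00154), the lysosomal list (0.00237), the cathepsin list (0.00306) and the toll-like receptor and NF-kappa-B list (0.00306). The elastic fibre list (0.00326), the matrix metalloproteinase list (0.00489), the proteoglycan list (0.0156) and the protease inhibitor list (0.0467) were also higher. The oxidative phosphorylation list (2.14e-09), the cardiomyocyte list (2.68e-06) and the immediate early and heat shock list (0.0164) were lower. The array means of the oxidative phosphorylation list overlapped between the 2 groups, and both group means lay above normal. For the immediate early and heat shock list the median log2 difference was only -0.0535 (mean -0.279). Adjusted over that list alone, 1 of its 19 members was higher and 2 were lower. The protease inhibitor call ended under 12 of 24 alternatives and the proteoglycan call under 6, both of them and the lysosomal call with age as a covariate, the cathepsin and elastic fibre calls ended without not dilated replicate 1, the cytokine call without dilated replicate 3, and the immediate early call with array quality weights.

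Macrophage genes were higher in MPS VII aortas, with a median log2 difference of 1.41 over the list. The camera adjusted p below use the preset correlation. With an estimated correlation the list did not pass without covariates (camera adjusted p = 0.32 in MPS VII minus normal and 0.282 in dilated minus normal). With the adipocyte mean as a covariate the macrophage median was 1.52 (camera adjusted p = 5.06e-10). In that fit 5 of the 21 members passed singly, while the median SE of the 2444 changed genes rose from 0.143 to 0.247. The adipocyte mean itself differed between the groups (9.93 in normal, 10.92 in dilated and 11.12 in not dilated aorta). Its slope thus rests on the few arrays within each group, and the fit cannot exclude fat in the samples as the cause. A lower share of smooth muscle cells would raise the markers of every other cell type alike. The macrophage median lay 1.79 above the fibroblast median of -0.39, although the endothelial and adipocyte medians were 0.54 and 1.27. The 95% bootstrap interval of the 1.79, 0.875 to 2.58, came from resampling the genes of the lists and not the mice. It therefore measures no spread between animals. The higher age of the dilated mice is argued against by the fit with age as a covariate, where the median in dilated minus normal was 2.04 against 1.86 (camera adjusted p = 2.46e-13). The age slope rests on few mice, however. The youngest dilated mouse, replicate 3, had the highest macrophage list mean relative to normal (2.23 against 1.56 and 1.54 in the other dilated aortas), which by itself raises the fitted difference. The disease, which the groups name, stays open as an explanation that was not tested.

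By camera's test with the preset correlation, adipocyte genes were higher in both MPS VII groups, and the cardiomyocyte list was higher without dilatation. With an estimated correlation neither list passed. The camera adjusted p were then 0.393 with and 0.461 without dilatation for the adipocyte list, and 0.137 for the cardiomyocyte list. A varying amount of fat around each aorta is a candidate explanation for the adipocyte rise. Within groups the adipocyte genes went up and down together over the 8 arrays, with a mean pairwise correlation of 0.594. It lay above all 1000 random lists (95th percentile 0.112). Some other lists went together at least as closely, with estimated correlations of 0.61 (contractile smooth muscle), 0.609 (oxidative phosphorylation) and 0.776 (MHC class II). The comparison with random lists therefore does not single out fat. Whether the MPS VII aorta carries more fat or was dissected with more of it stays open, as the samples do not separate these. Heart muscle in the samples stays open as a source of the higher cardiomyocyte list. Of 6 abundant heart muscle genes on the array, the highest in either aorta without dilatation was Myl7 at 96 units. However, Myh6, at 45.9 and 56.3, was higher in both than in the other 6 (7.45 to 33.5). Myl7 was brighter in dilated replicate 1 (162), and how bright a small share of heart muscle would be on these probes is not known.

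A chromosome segment carried along with the Gusb mutation could add changed genes near Gusb. Of the 100 measured genes nearest to it, 28% had changed in MPS VII minus normal, against 24.4% of 8854 others (odds ratio 1.2, 95% interval 0.746 to 1.89, one-sided Fisher's exact p = 0.237). The share near Gusb was slightly higher but did not pass the test, and the criterion set beforehand for excluding a segment asked for a share no higher as well as an interval under 2, so it was met only for the interval and a segment stays open.

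Of the 56 splits of the 8 arrays into 5 and 3, 1 gave as many changed genes as the real one. It was the real split itself, with 2387 genes against at most 8 in the others. For MPS VII minus normal this share lay under 0.05, the bound set beforehand, and 1 of 56 is the lowest these splits can give. The other splits mix arrays of both groups, which widens their spread and lowers their counts. The splits cannot tell the disease from other differences between the animals of the groups. For dilated minus normal the 10 splits of 6 arrays are too few for a share under 0.05, and 1 of them, the real one, gave as many as 2031 genes, against at most 0 in the others.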

How the results depend on the processing

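The offset of 100 and the adipocyte mean as a covariate were chosen after seeing the data. Gusb, Ms4a7 and Ccl21a stayed past the threshold in dilated minus normal under every alternative run, and the median over all genes moved by less than 0.1 under each of them. Dim genes limit the list results, since the offset of 50 shrinks differences near background. Where only 1 array without dilatation is left, it is assumed to vary like the other groups. The causes of the changes below were not tested.

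In dilated minus not dilated, 3 genes passed with normexp, 4 with no filter on dim probes, 3 with array quality weights, 19 with sex as a covariate, 3 with an offset of 100 and 1 with the adipocyte mean as a covariate. In dilated minus normal, array quality weights gave 3320. The adipocyte covariate gave 238 genes in dilated minus normal, 2 genes and 10 lists in not dilated minus normal, and 67 genes and 8 lists in MPS VII minus normal, where a fold of at least 1.5 left 1437. That covariate turned the direction of the oxidative phosphorylation list in dilated minus normal (camera adjusted p = 0.00178) and MPS VII minus normal (0.115), of the oxidative phosphorylation, contractile smooth muscle and cytokine lists in not dilated minus normal (0.903 each), and of Ctss (-0.0899) and Acta2 (0.228) in dilated minus normal and Acta2 (0.56) in not dilated minus normal. The value of Ctss, MPS VII not dilated minus normal, was 0.0603 with values floored at 16 and 0.0122 with cyclic loess. An estimated correlation left 0 lists in each of the 4 contrasts. Fry called 12 lists in dilated minus normal, 8 in not dilated minus normal, 1 in dilated minus not dilated and 15 in MPS VII minus normal.

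Leaving out each array in turn gave 1086 to 1954 genes in dilated minus normal, 81 to 1551 in not dilated minus normal, 0 to 3 in dilated minus not dilated and 1176 to 2405 in MPS VII minus normal, and correlations of the contrasts of 0.744 to 0.848. In not dilated minus normal it gave log2 differences of -0.317 to 0.0709 for Acta2, -0.24 to 0.187 for Ctss and -0.0752 to 0.178 for Ctsd, and camera adjusted p of 1.16e-06 to 0.585 for the T and NK cell list, and in dilated minus not dilated -0.105 to 0.487 for Eln. The fitted log2 difference of Gusb in dilated minus normal stayed at -2.26 to -2.14. With the sample number as a replicate block 1938, 859, 0 and 2313 genes passed, and the 7 pairs of arrays that share a number had correlations of their deviations of -0.193 to 0.333, 2 of them above 0.1, so the numbers are not read as pairs. A slide block was not run.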

Other observations

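The genes in this part were chosen after their values were seen. Ucp1, an uncoupling protein of mitochondria in brown fat, lay at 1250 to 10159 on the 8 arrays, with means of 2007 in normal aorta and 8337 in MPS VII aorta without dilatation (log2 difference 2.10, limma adjusted p = 0.0128), and its difference in dilated aorta was 0.80 (limma adjusted p = 0.0955). Cidea, a lipid droplet protein, lay at 3345 to 18234 and rose by 1.68 without dilatation (limma adjusted p = 0.0289). Of the globin genes, Hbb-b2 was below background in all 3 normal aortas and at 71.8 to 581 in the 5 MPS VII aortas, while Hba-a1 was bright in all groups, at 39837, 27419 and 52654 on average in normal, dilated and not dilated aorta.

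In dilated aorta Id1, a target of BMP signalling, fell by 1.37 (limma adjusted p = 0.00231). Of the autophagy genes, the cargo receptor Sqstm1 rose by 0.71 and Gabarapl1 by 0.93 (limma adjusted p = 0.0288 and 0.013), while Atg7 and Atg16l1, which act in autophagosome formation, had log2 differences of -0.59 and -0.54 (limma adjusted p = 0.0194 and 0.018).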
